A study of Homo sapiens with 4 samples.

How the data were processed

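Single-cell 3′ RNA libraries were made on the Chromium platform from HT29 and NCI-H508 cells, each with an empty vector or an LSD1 knockdown, per the labels. The 4 libraries fall into 4 groups of 1 by line and arm, as the labels name them. The deposited values are raw UMI counts for each gene and cell barcode: every value is a whole number, and totals differ between cells and libraries, so no normalization by the authors was found in them. The submitters' processing notes name Cell Ranger 3.1.0, Seurat 3.9.9.9014 and the build GRCh38. The filter behind the deposited barcodes and the annotation release are not given in the sources used here. Each file held 33538 genes by symbol, of which 33164 (98.9%) had a single place in GENCODE release 29 on GRCh38, the annotation used for coordinates and identifiers.

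The files held 11128 and 11310 barcodes for HT29 and 4944 and 6039 for NCI-H508, empty vector first. Cells with 500 or more genes and 25% or less mitochondrial UMIs were kept, which left 9873, 9808, 3929 and 4467 cells with 185853376, 179902246, 181900767 and 175242382 UMIs. Median mitochondrial shares were 6.80, 6.82, 10.4 and 11.0%, and 17.1, 15.3, 8.81 and 16.9% of cells held under 5000 UMIs. Doublets were scored with Scrublet as run by scanpy 1.11.5 (expected share 5%), but it called 1, 0, 0 and 0 cells, so that it did not work here. No doublets were removed, and leaving out the 5% of cells with the highest scores was an alternative.

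Counts were summed over the cells of each library and scaled to CPM by the library's total. Within a line, the ratio of the knockdown over the empty-vector library was given with an exact conditional binomial 95% interval, sums with exact Poisson intervals and shares with exact Clopper-Pearson intervals, all of which cover counting error only. Genes with 100 or more counts over the line's libraries and 5 CPM or more in 1 of them were counted as higher or lower when they were at least 2-fold apart. A group with 0 counts was set to a floor of 3 counts for a bound. For gene lists, members with 50 or more counts were used, and the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. List medians carry counting intervals from 1000 redraws. Lists with fewer than 5 measured members have no median.

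The 28 gene lists covered intestinal cell types (enteroendocrine, goblet, Paneth, tuft, absorptive, stem), S and G2/M phase, Notch, Wnt and growth factor signalling, the LSD1 complex, interferon, class I antigen presentation, NF-kB and chemokines, epithelial and mesenchymal genes, p53, the unfolded protein response, immediate early and heat shock genes, hypoxia and glycolysis, cholesterol synthesis, metallothioneins, mitochondrial and ribosomal genes, and fibroblasts, leukocytes and endothelium. Genes were named by a rule: per line KDM1A, the 12 largest ratios in each direction that passed the rule of size, and of each list up to 4 members at least 2-fold apart or else its 2 most abundant. Across lines the rule took up to 10 shared genes and up to 10 genes of the edgeR fit per direction. For shares of cells it took the 6 most abundant enteroendocrine and goblet genes of each line. A gene named in 1 line may be given in the other too, and of the genes so named only some are printed, and a few are not reported here. Genes outside the rule, named after their values were seen, are ISG15, the leading genes of clusters and the genes of the chromosome 14 segment. Listed symbols FAM64A, MLF1IP and TROY were read as PIMREG, CENPU and TNFRSF19, and HN1 of the G2/M list was not found. The lists, the rules of size and naming, the tests of genes and lists and most alternatives were set before the data were examined.

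Changes common to both lines were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM factors, filterByExpr, cell line as a term, 1 residual degree of freedom, Benjamini-Hochberg adjusted p under 0.05). Lists were tested with fry in limma 3.58.1. The p-values set a change against the spread between the responses of these 2 lines, not between replicates of a line. For single genes edgeR draws most of that spread from the trend over other genes. That trend had a median weight of 4.612 degrees of freedom, against 1 residual. A small p is therefore not measured agreement between the lines. Tested on simulated counts with the same fold in both lines, the fit recovered 65% of 2-fold and 93% of 4-fold changes, with 9 false calls among 17743 genes. On simulated pairs of libraries the rule of size found 100% of 3-fold and 0% of 1.5-fold changes, and the intervals covered the true ratio for 95.1% of genes in each line. These pairs were drawn from mean CPM and library totals, so that coverage was largely set by the draw. A gene's UMIs lying together in single cells were not simulated, and for such genes the intervals are too narrow.

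To compare shares of cells with a UMI and cell cycle phases, every cell was thinned to 5000 UMIs in HT29 and 10000 in NCI-H508, the largest depth tried that kept 80% of the cells of each library. This left out 1685 and 1500 HT29 cells and 409 and 850 NCI-H508 cells. Phases were called with scanpy from the S and G2/M lists, and a cell within 0.05 of a boundary on either score was counted as near it. Cells of each line were clustered on log values scaled to 10000 UMIs (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 0.5, igraph 0.11.9), without genes 1.5-fold or more apart between the line's libraries. A cluster's leading genes were those with the highest fold over other cells at 20 CPM or more.

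Alternatives were TMM and DESeq2 1.42.0 size factors, totals without mitochondrial and ribosomal genes, the mean of each cell's CPM, every deposited barcode, a stricter filter (1500 genes, 15% mitochondrial), cells called G1 among the thinned cells, minimums of 1 and 20 CPM, list members with 10 counts, DESeq2's test, no low-count filter, no cell line term, no thinning or thinning to 2000 UMIs, all variable genes, and resolutions 0.3 and 1.0. Chosen after seeing the data were cells of 5000 or more UMIs, leaving out the cell with the most UMIs of a gene, the subsets of the MUC2-led cluster, the list medians within clusters and without a cluster led by IFNL1, the cells of NCI-H508 clusters with at least 5 of 10 leading genes in the chromosome 14 segment, pooled under each clustering, and a scan of medians in windows of 50 neighbouring genes against 100 random gene orders. Singling out the clusters led by MUC2, IFNL1 and EAPP, and every test of an explanation in the closing section, came after seeing the data too. Under other clusterings the MUC2-led cluster was taken as the cluster with MUC2 among its 10 leading genes, also a later choice, and shares were judged by the ratio of the knockdown over the empty-vector share. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9. Free RNA was not estimated or removed, and no cell type names were given to clusters.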

Results

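Single-cell RNA sequencing was carried out on HT29 and NCI-H508, 2 established human colorectal cancer lines described as BRAF-mutant in the study's title. Each line carried either an empty vector or a knockdown of LSD1, the histone lysine demethylase encoded by KDM1A that works within corepressor complexes. The question addressed was whether lowering LSD1 alters the secretory cells of these lines, that is, cells with the goblet (mucus-producing) and enteroendocrine (hormone-producing) programmes of the intestinal epithelium. There was 1 library for each line and arm, 4 libraries in all. Total counts were 189394406 unique molecular identifiers (UMIs) in the HT29 empty-vector library and 184371840 in the HT29 knockdown library. The NCI-H508 empty-vector library held 188071486 and its knockdown library 183015881. After filtering, 9873 and 9808 HT29 cells and 3929 and 4467 NCI-H508 cells remained, empty vector first. Median depth was 18439 and 18154 UMIs per cell in HT29, and 38506 and 33647 in NCI-H508. Within a line a difference has no replicate check, so no p-value is given there, and every 95% interval on counts or shares covers counting error only.

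KDM1A (ENSG00000004487, plus strand of chromosome 1, 23019443 to 23083689 on GRCh38) was lower in the knockdown library of both lines. In HT29 it stood at 67.3 CPM (UMI counts scaled to a common library total) with the empty vector and 8.42 CPM with the knockdown, 12.5% of control (interval 11.8 to 13.2%). In NCI-H508 it stood at 54.3 and 12.6 CPM, 23.3% of control (22.2 to 24.4%). The share of HT29 cells with a KDM1A UMI was 27.9% and 4.36% after each cell was thinned to 5000 UMIs, and 59.0% and 12.3% before thinning. In NCI-H508, thinned to 10000 UMIs, it was 41.5% and 11.2%, and 77.0% and 29.3% before thinning.

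In HT29, several marker genes of both secretory programmes were lower in the knockdown library. MUC2, the main gel-forming mucin of goblet cells, was 71.4 CPM with the empty vector and 2.96 CPM with the knockdown, 24.1-fold lower (22.1 to 26.3). FCGBP, a mucus-binding protein, was 11.5-fold lower (10.7 to 12.3), SPINK4 10.3-fold lower, and TFF3, the goblet trefoil factor, 6.66-fold lower at 299 and 44.8 CPM. PAX4, a transcription factor of endocrine lineages, was 27.0-fold lower (20 to 37.4), and INSM1, an endocrine transcription factor that recruits LSD1, was 5.34-fold lower. The hormone genes SST (somatostatin) and GCG (glucagon) were 65.4-fold (48.8 to 89.9) and 44.5-fold (17.1 to 165) lower, the second with 4 counts in the knockdown library. SST rested on few cells, since 1 of the 86 positive empty-vector cells held 38.1% of its UMIs and 1 knockdown cell held 86.7%. Without the top cell of each library SST was 304-fold lower (139 to 828), outside the interval above.

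Of the 20 enteroendocrine genes measured in HT29, 13 were at least 2-fold lower and 3 at least 2-fold higher. Their median log2 ratio was -1.82, at percentile 0 of 10000 random lists matched on expression, whose central 95% ran from -0.12 to 0.53. Here and below such a percentile is not a test of the knockdown. It holds no spread between replicates and treats the genes of a list as independent, so small medians can also reach its extremes. The sum over the list, which its abundant members set, was 61.9 and 49.4 CPM (ratio 0.798). SCG5, a neuroendocrine chaperone, went the other way, from 4.71 to 16.6 CPM. Of the 30 goblet genes, 12 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -0.28, again at percentile 0 (random range -0.0061 to 0.35). At any size 14 were higher and 16 lower, and the sum over the list, which its abundant members set, was 2334 and 2707 CPM. ATOH1, the master regulator of secretory fate, was 2.49-fold lower. AGR2, a disulfide isomerase for mucins, was 1.51-fold higher, and SPDEF, a goblet maturation factor, stood at 47.9 and 50.3 CPM. Among Notch pathway genes, 7 of 20 were at least 2-fold lower and 0 higher (median -0.82, percentile 0), including the ligand DLL1 (7.66-fold), which secretory precursors express, and HES6 (4.08-fold, 243 to 59.6 CPM).

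**Figure D1:**
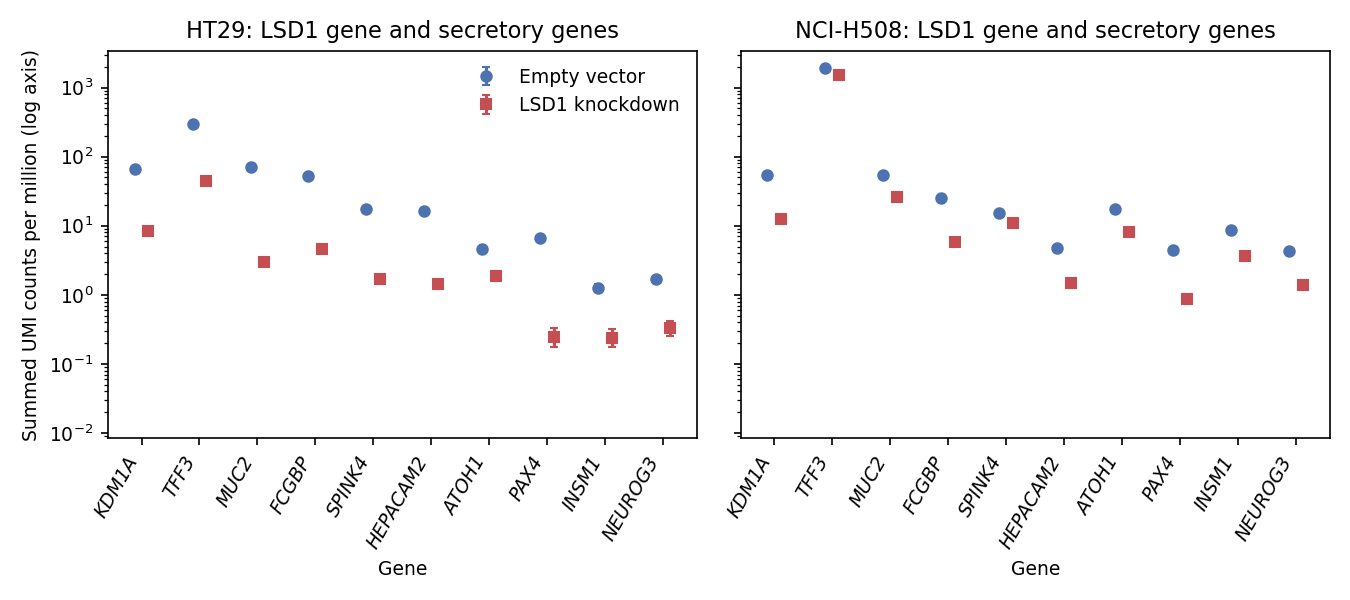
KDM1A and 9 genes of secretory cells in each line, as counts summed over the cells of a library, in CPM on a log axis. Circles are the empty-vector library and squares the knockdown library, 1 library each, with exact 95% Poisson intervals that cover counting error only and are mostly smaller than the symbols. MUC2 was 71.4 and 2.96 CPM in HT29 and 54.0 and 26.1 CPM in NCI-H508.

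Interferon-stimulated genes were the list with the most members at least 2-fold higher in HT29. IFI6, a mitochondrial interferon response protein, was 379 and 1980 CPM, 5.22-fold higher (5.18 to 5.26). IFITM3, which restricts viral entry, was 5.53-fold higher, and OAS2, a sensor of double-stranded RNA, 5.06-fold higher. Of the 42 genes of the type I interferon list, 30 were at least 2-fold higher and 0 lower (median 1.31, percentile 100). Antigen presentation genes were higher too, with 7 of 18 at least 2-fold higher and 0 lower (median 0.74, percentile 100), among them HLA-B (5.5-fold) and the immunoproteasome subunit PSMB9 (4.25-fold). Metallothioneins, which bind zinc and copper, had a median of 1.78 (percentile 100), with 4 of 7 at least 2-fold higher, MT2A from 10.7 to 102 CPM. Of the NF-kB and chemokine genes, 7 of 21 were at least 2-fold higher and 0 lower (median 0.38, percentile 96.7), including CCL20 (9.69-fold) and CXCL1 (6.84-fold).

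Cell cycle genes were higher in the HT29 knockdown library. All 43 S-phase genes had a higher value and 25 were at least 2-fold higher (median 1.08, percentile 100), such as the replication helicase subunit MCM4, 14.2 and 44.2 CPM, and CLSPN, 8.90 and 29.1 CPM. All 53 genes of the G2/M list were also above the empty vector, 16 by at least 2-fold (median 0.79, percentile 100), such as the mitotic kinesin KIF11 (2.37-fold). CDKN1C, an inhibitor of cyclin-dependent kinases, was 8.31-fold lower. Among thinned cells, those called G1 made up 81.1% (80.2 to 81.9) of the empty-vector library and 60.1% (59.1 to 61.2) of the knockdown library. S-phase calls were 4.74% and 12%, and G2/M calls 14.2% and 27.9%. Calls lay near a boundary between phases for 14% and 21.9% of these cells, and free RNA, which such calls also read, was not removed, so its part in them is open.

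Among HT29 genes above the abundance minimum of 5 CPM in 1 library, those highest over control were TNNT1, a slow skeletal troponin (7.73 and 136 CPM, 17.7-fold, 16.7 to 18.6), the membrane protein EMP3 (15.9-fold) and the transferrin family member MELTF (11.2-fold). They were followed by UBE2L6 (10.6-fold) and IFI16 (10.4-fold), both interferon-inducible, then DHRS2 (8.42-fold), CPVL (8.34-fold), CAV1 (7.60-fold) and LGALS1 (7.37-fold). Below that minimum, LGR5, an intestinal stem cell receptor, was 14.8-fold higher (10.3 to 22.0) from 0.167 CPM, and SAA1, a serum amyloid gene, 55.8-fold higher (9.60 to 2244) from 1 and 54 counts. At the other end, beside the secretory genes, stood the kinase gene CAMK2B (23.8-fold lower), the trypsinogens PRSS2 (15.2-fold) and PRSS1 (14.5-fold), HEPACAM2 (11.5-fold) and ZNF114 (9.94-fold). PRSS1 and PRSS2 are near-identical copies, so the division of reads between them is uncertain.

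By the fixed rule of size, 550 of 10045 HT29 genes were at least 2-fold higher and 97 at least 2-fold lower, so that 85.0% of them were higher. The median of all compared genes was itself 0.16 log2 above 0, and random lists were centred close to that shift. With TMM factors the shift was 0.0096, and 362 genes were higher and 151 lower, 70.6% higher. The ribosomal protein genes lay below it, with 71 of 83 lower (median -0.38, percentile 0) and 0 by 2-fold.

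In NCI-H508 several secretory marker genes were again lower in the knockdown library. FCGBP was 25.4 and 5.88 CPM, 4.32-fold lower (4.04 to 4.62), MUC2 54.0 and 26.1 CPM, 2.07-fold lower (2.0 to 2.15), and PAX4 4.49 and 0.884 CPM, 5.07-fold lower (4.27 to 6.06). NEUROG3, the factor that commits progenitors to the endocrine lineage, was 3.12-fold lower (2.70 to 3.62), INSM1 2.34-fold, ATOH1 2.18-fold and SPDEF 2.16-fold lower. Of the 16 enteroendocrine genes measured, 8 were at least 2-fold lower and 0 higher (median -0.97, percentile 0, sum over the list 98.9 and 79.3 CPM), including SCGN (6.26-fold) and SCG2 (5.72-fold). CHGA, the secretory granule protein chromogranin A, was 17.7-fold lower, with 42.9% of its 147 empty-vector UMIs in 1 cell. Of the 29 goblet genes, 9 were at least 2-fold lower (median -0.46, percentile 0) and 5 were higher at any size. The lower ones included REP15 (3.35-fold), B3GNT6 (3.48-fold) and RETNLB (2.68-fold). ZG16, a goblet lectin, was the 1 goblet gene at least 2-fold higher, at 4.79 and 12.3 CPM. CLCA1 was 7.47-fold lower, with 33.9% of its empty-vector UMIs and 75% of its 16 knockdown UMIs in 1 cell each.

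Outside the secretory programmes, the largest ratios in NCI-H508 among genes above the same abundance minimum belonged to TNC, the matrix protein tenascin C, which was 0.0825 and 8.46 CPM (103-fold higher, 62.0 to 184), and CCDC88A, an actin-binding regulator of migration (20.6-fold). TESC (15.9-fold), the membrane-cytoskeleton linker MSN (15.8-fold), the G1 cyclin CCND2 (14.9-fold), TNNT1 (12.8-fold), KISS1R (11.1-fold) and the actin bundler FSCN1 (10.6-fold) followed. CDA (6.73-fold), KLK10 (6.51-fold) and MT1G (6.11-fold) were also among the largest. OLFM4, a stem cell glycoprotein, was 7.20 and 0.245 CPM, 29.3-fold lower (21.6 to 40.7). REG4 was 2.95-fold, DLL1 2.66-fold and CADPS, a factor of dense-core vesicle release, 2.19-fold lower. CRYAB was 136-fold lower, but 1 empty-vector cell held 97.7% of its 1971 UMIs, and without the top cell of each library it was 3.33-fold lower (1.77 to 6.74).

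Metallothioneins (5 of 7 at least 2-fold higher, median 1.46, percentile 100) and NF-kB and chemokine genes (8 of 21, median 0.63, percentile 100) stood above random lists in NCI-H508, with 0 members 2-fold lower. MT1H was 12.2-fold higher (7.55 to 21.0), CXCL1 3.35-fold and CCL20 2.95-fold. SAA1 was 6.90-fold higher, but 71.4% of its 14 empty-vector UMIs lay in 1 cell. Of 23 Wnt target genes 4 were at least 2-fold higher and 0 lower (median 0.15, percentile 99.8), with LGR5 at 2.63 and 12.4 CPM, SP5 2.70-fold and EPHB3 2.31-fold higher. S-phase and G2/M genes were slightly higher (medians 0.21 and 0.24, both percentile 100), with 0 of 43 and 0 of 53 by 2-fold, PCNA at 86.7 and 103 CPM and CKS2 at 187 and 221 CPM. Cells called G1 were 68.5% (67.0 to 70.1) and 59.8% (58.2 to 61.4) after thinning, S-phase calls 7.50% and 10%, and G2/M calls 24.0% and 30.2%. The interferon list showed no such shift (34 genes, median 0.03, percentile 79.7, 1 at least 2-fold higher and 1 lower). IFIT3 was 0.269 and 0.924 CPM, and the 51 UMIs of CXCL10 all lay in 1 empty-vector cell. By the rule of size 69 of 9629 genes were at least 2-fold higher and 15 lower, and the median of all genes was 0.00044.

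Cells were then clustered in each line without the genes that differed 1.5-fold or more between its libraries, MUC2 and FCGBP among those left out. Each line had a cluster whose leading genes by fold over other cells were MUC2 and FCGBP. Genes from the lists of several cell classes led it, goblet and endocrine in both lines and absorptive (GUCA2A, GUCA2B) in HT29. In NCI-H508 REG4 and SPINK4 of the Paneth list were among its leading genes. SPINK4 is on the goblet list too, so only REG4 came from the Paneth list alone. The cluster was left unnamed in each line. In HT29 it held 967 of 9873 empty-vector cells, 9.79% (9.21 to 10.4), and 364 of 9808 knockdown cells, 3.71% (3.35 to 4.10), a share 2.64-fold lower (2.34 to 2.99). In NCI-H508 it held 312 of 3929 cells, 7.94% (7.11 to 8.83), and 124 of 4467, 2.78% (2.31 to 3.30), 2.86-fold lower (2.32 to 3.55). Within the HT29 cluster MUC2 was 799 CPM in empty-vector cells and 51.7 CPM in knockdown cells, FCGBP 592 and 114 CPM, TFF3 3112 and 936 CPM and PAX4 73.9 and 5.22 CPM. Within the NCI-H508 cluster MUC2 was 775 and 1008 CPM, SPINK4 196 and 448 CPM, FCGBP 362 and 242 CPM, TFF3 6216 and 6133 CPM and PAX4 75.3 and 40.2 CPM. Singling out this cluster was a choice made after the clusters were seen.

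Shares of cells with a UMI of single marker genes went both ways in HT29, where 8 of the 12 genes compared had a higher share in the knockdown library and 4 (PAX4, TFF3, SYP and SST) a lower one. In NCI-H508, 2 of 12 had a higher share and 10 a lower one, of which DDC (47.0% and 46.1%), AGR2 (76.1% and 75.2%) and MUC13 (72.2% and 71.5%) had overlapping intervals (unthinned 78.8% and 71.0%, 86.3% and 81.5%, and 88.0% and 81.6%). After thinning, 1.95% (1.67 to 2.28) of HT29 empty-vector cells and 0.156% (0.0833 to 0.267) of knockdown cells had a PAX4 UMI (2.72% and 0.214% unthinned). For TFF3 the shares were 22.3% and 7.27% (42.1% and 15.5% unthinned), and for SYP, a vesicle protein, 4.01% and 1.3% (9.21% and 4.59%). The shares were higher for SCG5, at 2.66% and 7.91%, and for AGR2, at 87.5% and 95.6% (unthinned 5.24% and 19.6%, and 94.1% and 97.3%), and for GCNT3 (47.1% and 68.7%), SPINK1 (35.0% and 50.8%), ISL1 (3.36% and 6.38%), DDC (2.75% and 5.5%), MUC13 (44.8% and 50.9%) and AGR3 (29% and 34.7%). Unthinned, these 6 were 74.6% and 86.3%, 56.1% and 71.9%, 10.6% and 19.5%, 9.18% and 16.8%, 70.4% and 77.1%, and 47.7% and 57.3%. In NCI-H508 NEUROG3 was seen in 2.64% (2.14 to 3.23) and 0.940% (0.652 to 1.31) of cells, PAX4 in 1.90% and 0.470%, INSM1 in 3.64% and 1.85% and CPE, a prohormone-processing enzyme, in 2.93% and 1.08%. Unthinned, these were 4.23% and 1.25%, 3.28% and 0.672%, 6.18% and 2.66%, and 6.77% and 2.78%. The 2 genes with a higher share were GCNT3 (35.5% and 45.3%) and KLK1 (25.2% and 35.5%), unthinned 64.2% and 64.8%, and 58.0% and 60.7%. For comparison, shares were also taken in the cluster of each line with the largest share of cycling cells, called the proliferating cluster here. In NCI-H508 this held 96.2% cycling cells. Another cluster there, led by FAM111B and HIST1H1B, held 94.4% and was not used. Cells of the proliferating cluster may make these RNAs themselves, so such shares cannot separate free RNA from the cells' own expression. In HT29 that cluster showed PAX4 in 0.324% of empty-vector cells and 0 of 2590 knockdown cells, with an exact interval up to 0.142%, and TFF3 in 17.0% and 5.41%, at median depths of 26317 and 24754 UMIs before thinning. There it also showed SYP in 1.51% and 1.20%, SCG5 in 1.19% and 4.90%, AGR2 in 86.5% and 94.6%, GCNT3 in 48.4% and 66.5%, SPINK1 in 33.8% and 47.3%, ISL1 in 3.46% and 6.83%, DDC in 4.32% and 5.52%, MUC13 in 32.2% and 47.7% and AGR3 in 24.7% and 32.4%. Since the proliferating cells were higher in the knockdown library for all 8 genes with higher shares, a higher share of all cells does not by itself mean more marker cells. TFF3 was lower in the proliferating cells too, so its lower share of all cells does not by itself mean fewer marker cells. In the MUC2-led cluster PAX4 was seen in 13.7% and 3.34%, TFF3 in 87.0% and 62.7%, SYP in 18.5% and 1.67% and SCG5 in 16.6% and 34.8%, at 14232 and 14342 UMIs. In NCI-H508 the proliferating cluster showed NEUROG3 in 0.205% and 0.457%, INSM1 in 1.43% and 0.457%, CPE in 1.43% and 0.762%, PAX4 in 0 of 488 and 0 of 656 cells (exact intervals up to 0.753% and 0.561%), KLK1 in 13.5% and 25% and GCNT3 in 41.4% and 44.2% of cells (49306 and 44608 UMIs), and the MUC2-led cluster NEUROG3 in 27.7% and 21.3% and INSM1 in 34.5% and 41.8%, CPE in 22.6% and 13.9% and PAX4 in 19.6% and 13.1% (24775 and 23134 UMIs). The higher shares of KLK1 and GCNT3 carry the same limit as in HT29. INSM1 and CPE were lower in the proliferating cluster too, but in few cells (7 and 3 for INSM1, 7 and 5 for CPE).

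**Figure D2:**
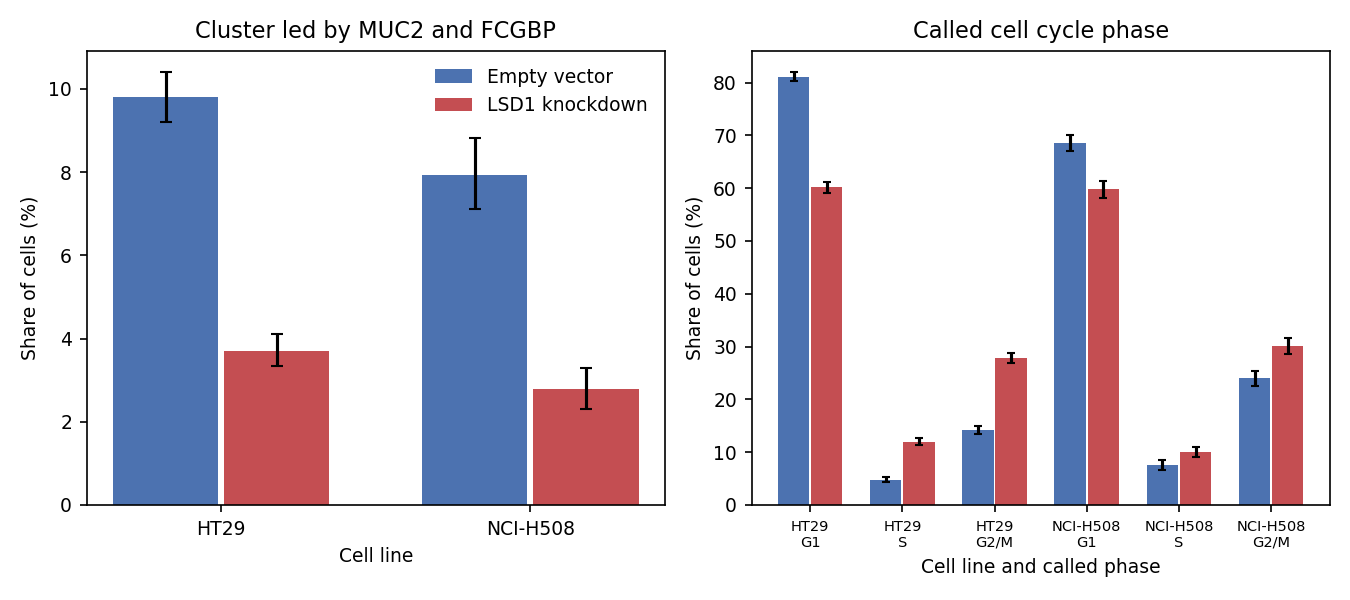
Left, share of cells in the cluster led by MUC2 and FCGBP, in percent of the cells of each library. Right, share of cells called G1, S or G2/M after thinning, in percent. Bars are single libraries, empty vector and LSD1 knockdown, with exact 95% binomial intervals that cover counting error only. The cluster's share was 9.79% and 3.71% in HT29 and 7.94% and 2.78% in NCI-H508.

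The lines were compared across the 8899 genes measured in both. Genes at least 2-fold higher in both numbered 22, where independent lists would share 1.46, and genes at least 2-fold lower in both numbered 3, KDM1A, MUC2 and FCGBP, where 0.0290 would be shared. No gene was 2-fold apart in opposite directions among them (0 of 8899). Independent lists would share only 0.225 (higher in HT29, lower in NCI-H508) and 0.188 (the reverse), so this 0 says little. Shared higher genes included TNNT1, LGALS1, CAV1, MT2A and CCL20, with the lowest of these ratios 2.95-fold in NCI-H508, and ADIRF (2.97-fold and 3.46-fold, HT29 first), ACY3 (3.63-fold and 3.19-fold), FKBP5, a glucocorticoid-induced chaperone (2.84-fold and 3.27-fold), and TRIM29 (2.77-fold and 3.29-fold). Below the abundance minimum in 1 or both lines, VIM, the mesenchymal filament vimentin, was 13.3-fold higher in HT29 (0.253 and 3.36 CPM) and 18.2-fold higher in NCI-H508 (0.0330 and 0.599 CPM). Across genes, which are not independent replicates, the log2 ratios had a Pearson r of 0.416 and a Spearman rho of 0.367.

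With the lines as the replicates, edgeR's quasi-likelihood test (2 libraries against 2, cell line as a term, 1 residual degree of freedom, Benjamini-Hochberg adjustment over 17994 genes) called 4 genes higher and 1 lower. TNNT1 (chromosome 19, 55132794 to 55149354) rose 14.2-fold (adjusted p = 0.0137) and LGALS1, the lectin galectin 1 (chromosome 22, 37675608 to 37679806), rose 5.94-fold (adjusted p = 0.0358). AKAP12, a kinase scaffold (chromosome 6, 151239999 to 151358557), rose 7.68-fold (adjusted p = 0.0405). These 3 were higher in both lines, but 1 NCI-H508 knockdown cell held 56.5% of the AKAP12 UMIs there, and without the top cells the ratio in that line was 6.80-fold (5.02 to 9.38). SST (chromosome 3, 187668906 to 187670399) was called lower (adjusted p = 0.0358) from HT29 alone, since NCI-H508 had 3 and 0 counts. At an unadjusted p under 0.05, 1125 genes were higher and 553 lower, and DESeq2 called 182 and 33 at an adjusted p under 0.05. Other edgeR fits went both ways at that level. They called 1 higher and 0 lower under the stricter cell filter, and 4 and 0 on cells of 5000 or more UMIs. With RLE factors, another library scaling, edgeR called 4 and 1, and without a low-count filter 187 and 53. Without the cell line term edgeR called 0 and 0. The edgeR test recovered 65% of simulated 2-fold changes and 93% of 4-fold changes, but each simulated change had the same fold in both lines. Recovery where the lines' folds differ was not simulated. KDM1A, MUC2 and FCGBP, each at least 2-fold lower in both lines, were not called by the main edgeR fit.

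None of 27 lists tested across both lines with fry passed Benjamini-Hochberg adjustment (0 of 27, smallest adjusted p = 0.207, for the Notch and the LSD1 complex lists), and 4 had an unadjusted p under 0.05, these and the NF-kB and leukocyte lists. The LSD1 complex list holds KDM1A itself, so its result is in part the knockdown. For the enteroendocrine list the adjusted p was 0.294 and for the goblet list 0.268, and the lists' medians in that fit were -1.45 and -0.53. Adjusted over the list alone, 8 enteroendocrine genes were lower and 1 higher, 6 goblet genes lower, 9 NF-kB and chemokine genes higher, 11 interferon genes higher, 4 metallothioneins higher and 4 Wnt targets higher. Adjusted over all genes, SST was the 1 list member called among these. In NCI-H508 alone the interferon list showed no shift (median 0.03, 1 of 34 genes at least 2-fold higher and 1 lower). The 11 interferon calls therefore do not show a rise of that list common to both lines. Nor does any of these list-alone calls by itself show a change in both lines, since each gene's spread came mostly from other genes.

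**Figure D3:**
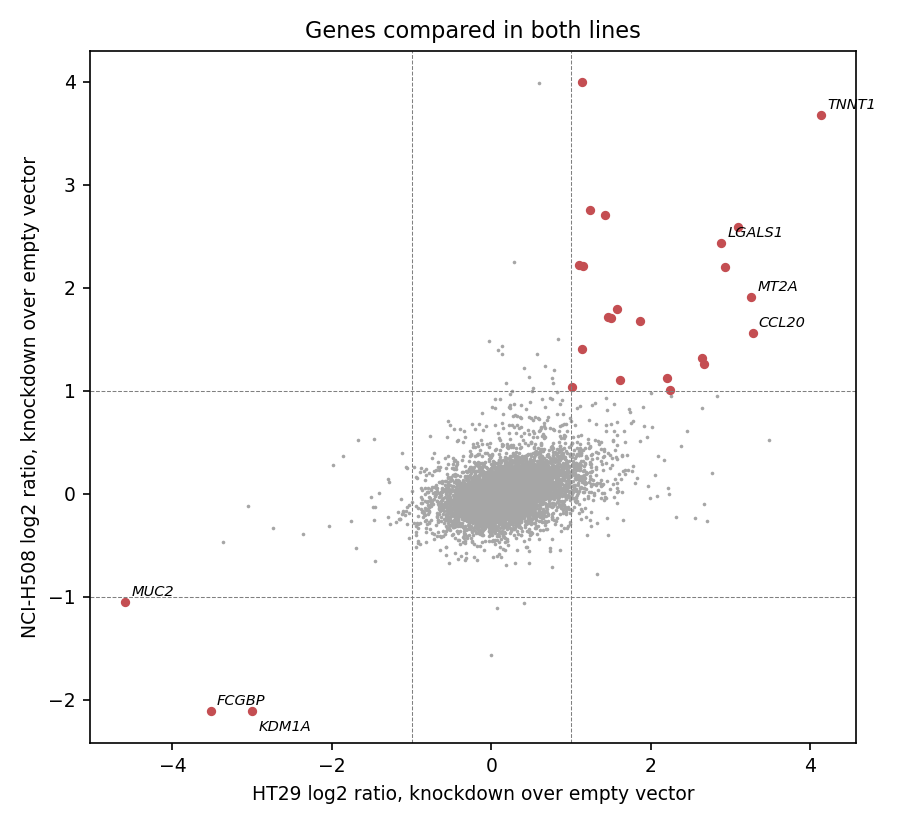
Log2 ratio of the knockdown over the empty-vector library for each of the genes measured in both lines, HT29 on the horizontal and NCI-H508 on the vertical axis. Points are genes, dashed lines mark 2-fold, and larger points are the 22 genes higher and 3 genes lower by at least 2-fold in both lines.

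In HT29 the stem cell list had a median of 0.34 (percentile 96.5) and in NCI-H508 0.11 (percentile 99.1, 3 of 24 at least 2-fold higher and 1 lower, SMOC2 4.86-fold higher). Tuft cell genes had medians of 0.72 (percentile 97.0, 8 genes, POU2F3 2.63-fold higher) and 0.37 (percentile 96.3, DCLK1 4.88-fold higher with 47.1% of its 17 empty-vector UMIs in 1 cell). Absorptive genes had a median of 0.11 in HT29 (percentile 31.1), which turned negative with TMM factors, with 5 of 24 at least 2-fold lower including GUCA2B (5.43-fold) and 2 higher. In NCI-H508 their median was -0.19 (percentile 0), with DPP4 4.24-fold higher, FABP2 2.78-fold lower and AQP8 4.40-fold lower, of whose 352 empty-vector UMIs 36.6% lay in 1 cell. The epithelial-mesenchymal list was at 0.12 in HT29 (percentile 33.8, negative with TMM factors, 7 of 28 at least 2-fold higher and 3 lower, TGFBI 3.18-fold lower) and at 0.19 in NCI-H508 (percentile 100, 4 of 25 higher and 0 lower, PLAU 3.14-fold). Epithelial genes were at -0.11 (percentile 0.27) and -0.086 (percentile 0.04), with KRT8 at 4025 and 4634 CPM in HT29. Notch genes in NCI-H508 were at -0.16 (percentile 0.13).

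Unfolded protein response genes had medians of -0.28 in HT29 (percentile 0, 3 of 24 at least 2-fold lower, DDIT4 3.40-fold, CHAC1 3.09-fold and DDIT3 2.78-fold) and -0.078 in NCI-H508 (percentile 0.43). Immediate early and heat shock genes were at -0.31 (percentile 0, EGR2 4.47-fold lower and HSPB1 2.34-fold higher) and -0.10 (percentile 0.03). The p53 targets were at -0.14 (percentile 0.11), with GDF15 2.66-fold lower and FAS 3.25-fold higher, and at 0.075 (percentile 94.7). Hypoxia and glycolysis genes were at -0.057 (percentile 0.50, CA9 3.06-fold higher) and -0.070 (percentile 1.29, SLC2A3 3.72-fold higher). Growth factor signalling output was at 0.17 (percentile 55.3, AREG 2.43-fold lower and ETV1 2.81-fold higher) and -0.024 (percentile 25.3). Wnt targets in HT29 were at 0.18 (percentile 53.6), with DKK1 2.91-fold higher and NOTUM 3.37-fold lower. Cholesterol synthesis was at 0.20 (percentile 81.9) and 0.052 (percentile 87.0), and the LSD1 complex list at 0.17 (percentile 57.9) and -0.077 (percentile 1.95), with RCOR2 2.60-fold lower and ZEB2 2.79-fold higher in HT29. Mitochondrially encoded genes were at 0.10 in HT29 (percentile 48.8, negative with TMM factors) and 0.12 in NCI-H508 (percentile 96.9). Class I antigen presentation in NCI-H508 was at 0.17 (percentile 99.96), with 0 of 18 by 2-fold, and ribosomal protein genes there at -0.060 (percentile 0).

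Lists for other cell types had few measured members. In HT29, 5 of 14 leukocyte genes were measured (median 0.99, percentile 99.4), the most abundant being LYZ, lysozyme, which the Paneth list also holds, at 2009 and 6131 CPM. CD52 was 3.79-fold higher from 1.90 CPM. Of the fibroblast and endothelial lists 4 of 12 and 2 of 10 genes were measured in HT29, too few for a median, with LUM at 2.27 and 4.29 CPM and PECAM1 at 0.382 and 1.60 CPM. In NCI-H508 4 leukocyte genes, 3 fibroblast genes and 1 endothelial gene were measured, with COL1A1 at 4.28 and 5.70 CPM.

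**Figure D4:**
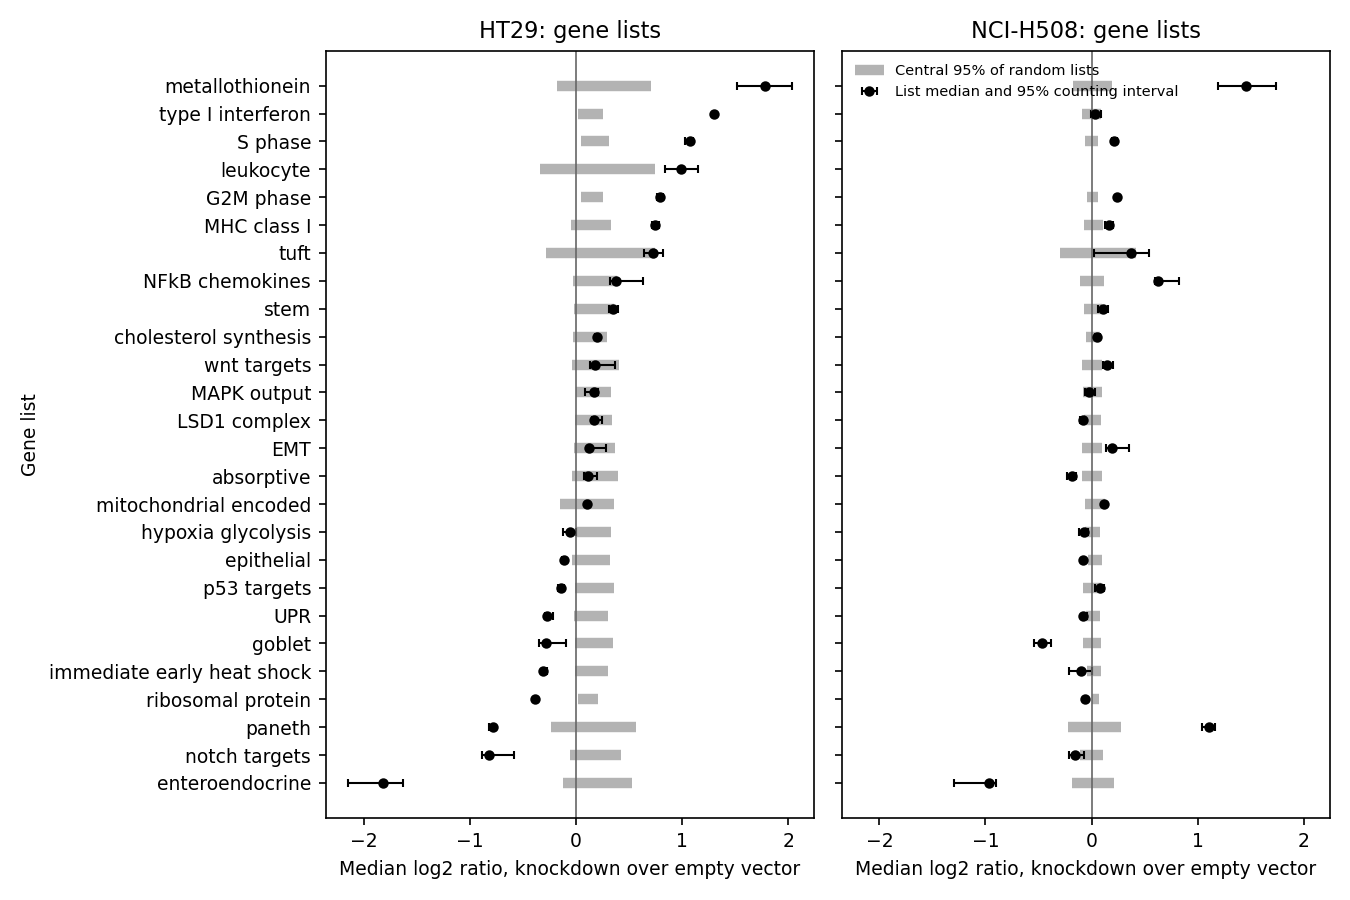
Median log2 ratio, knockdown over empty vector, of each gene list with at least 5 measured members, in HT29 and NCI-H508. Points are list medians with 95% counting intervals and grey bars the central 95% of 10000 random lists of the same size and expression. The enteroendocrine list lay at -1.82 in HT29 and -0.97 in NCI-H508, and the interferon list at 1.31 and 0.03.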

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

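The results here went in opposite directions in HT29 and NCI-H508, and the difference between the lines was not tested, since each line had 1 library per arm. The Paneth-cell list, genes of antimicrobial and protease secretion, had a median log2 ratio of -0.78 in HT29 (6 genes, 1 at least 2-fold higher and 3 lower, percentile 0 of random lists) and 1.10 in NCI-H508 (7 genes, 4 higher and 2 lower, percentile 100), a difference of 1.88. The measured members were not the same, with PRSS2 in HT29 alone and DEFA5 and DEFA6 in NCI-H508 alone, and the sums, which abundant members set, went the other way, 2548 and 6352 CPM in HT29 and 69.4 and 65.5 CPM in NCI-H508. Among its members LYZ was higher in both lines (3.05-fold and 2.15-fold), PLA2G2A was 2.84-fold higher in NCI-H508, and DEFA5 was at least 46.7-fold higher there, although 1 cell held 131 of its 135 UMIs. MMP7, matrilysin, was 435 and 148 CPM in HT29 (log2 ratio -1.56) and 0.330 and 1.83 CPM in NCI-H508 (2.47), a difference of 4.03. ZG16, the goblet lectin, had log2 ratios of -3.80 and 1.36, a difference of 5.16, with 50.5% of its 101 HT29 empty-vector UMIs in 1 cell. ZNF114, a zinc finger gene, had log2 ratios of -3.31 and 1.03, a difference of 4.34, from 31 and 61 counts in NCI-H508.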

How the results depend on the processing

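Of the alternatives, the subset of cells with 5000 or more UMIs, the G1 subset of the cluster shares and the joint share of split clusters were chosen after seeing the data. The enteroendocrine medians kept direction and size in both lines under all 10 alternatives run, the KDM1A ratio in NCI-H508 under 9, and the phase ratios under 4 each apart from the S-phase ratio in HT29, which was 2.18 without thinning. The causes of the shifts below were not tested unless named. The KDM1A ratio in HT29, 0.125, was 0.114 with DESeq2 factors, 0.113 with TMM, 0.115 without mitochondrial and ribosomal genes in the totals, 0.138 in G1 cells and 0.139 as the mean of each cell's CPM.

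The counts of 2-fold genes followed the abundance minimum, which sets how many genes are compared. At 1 CPM they were 929 higher and 214 lower in HT29 and 221 and 47 in NCI-H508, and at 20 CPM 267 and 41, and 23 and 5. Scaling, which moves the median of all genes in HT29, gave 362 higher and 151 lower there with TMM, 146 lower with DESeq2 factors and 170 lower without mitochondrial and ribosomal genes. With the mean of each cell's CPM, 23 genes were lower in NCI-H508. The goblet median in HT29 was -0.42 with DESeq2 factors, -0.43 with TMM, -0.46 as the mean of each cell's CPM, -0.44 with members of 10 counts and -0.41 without mitochondrial and ribosomal genes, and in NCI-H508 -0.63 as the mean of each cell's CPM. Pearson's r between the lines was 0.458 at 20 CPM, 0.377 in G1 cells, 0.440 as the mean of each cell's CPM and 0.434 without mitochondrial and ribosomal genes.

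The calls common to both lines depended on the test, with adjusted p under 0.05 throughout. DESeq2 called 182 genes higher and 33 lower (3489 left without an adjusted p), edgeR without a low-count filter 187 and 53, edgeR on every barcode 2 higher, edgeR under the stricter cell filter 1 and 0, and edgeR on cells of 5000 or more UMIs 0 lower. Without the cell line term, the pairing of libraries by line, 0 were higher and 0 lower, with 27 and 13 at an unadjusted p under 0.05. The 5 genes were all among the calls of DESeq2 and of the unfiltered edgeR fit.

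The MUC2-led cluster's share ratio in HT29 was 0.315 with all variable genes, 0.558 at resolution 0.3 and 0.492 in G1 cells, and in NCI-H508 0.435 at resolution 0.3 and 0.465 in G1 cells. Directions turned for a few values close to 0 in HT29. With DESeq2 factors, TMM, and without mitochondrial and ribosomal genes, the mesenchymal list median was -0.0102, -0.0257 and -0.00114, the absorptive median -0.0196, -0.0352 and -0.0106, and the mitochondrial median and MT-CO2 each -0.0337, -0.0492 and -0.0246. MT-CO2 was -0.00174 as the mean of each cell's CPM. In NCI-H508 the share ratio of the cluster led by EAPP, 1.41, was 0.904 at resolution 1.0, where its cells were split over 2 clusters whose joint ratio was 1.04 (0.928 to 1.17), and 1.05 (0.939 to 1.18) with all variable genes. For the named genes, 1885 of 1889 values under alternatives kept direction and 1438 also stayed within their counting interval. Of the other list medians, 120 of 216 in HT29 and 160 of 207 in NCI-H508 stayed within it, as did 40 and 41 of 52 marker shares per line. Of 33 fold changes of the genes called in both lines, 23 stayed called and 10 did not, all in the same direction. The share of the IFNL1-led cluster in HT29, knockdown over empty vector, was 8.38 as a ratio, 5.76 with all variable genes and 4.81 at resolution 1.0, and no cluster was led by IFNL1 at resolution 0.3. Depth limits most the genes under 1 CPM, whose ratios rest on few UMIs and at times on single cells.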

Other observations

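KDM1A was itself unevenly spread over HT29 cells. With the empty vector it was 131 CPM (125 to 137) inside the MUC2-led cluster and 62.1 CPM (60.9 to 63.2) elsewhere, and with the knockdown 26.8 and 7.83 CPM. In NCI-H508 it was 71.3 and 53.4 CPM with the empty vector and 11.9 and 12.6 CPM with the knockdown. Several other HT29 clusters were mostly of 1 library although genes that differed were left out, so they may stand for a library rather than a cell type (1 library per arm, which leaves a difference between single libraries other than the knockdown open). A cluster led by KRT17 and ITPKA held 38.9% of empty-vector and 3.30% of knockdown cells, one led by MMP7 and ARRDC4 17.9% and 0.897%, and one led by TNNT1 and SLPI 2.25% and 39.6%. Knockdown cells made up 7.78, 4.75 and 94.6% of these clusters, and 89.3% of the one led by IFNL1 below. The cluster of mitotic genes, led by UBE2C and CCNA2, held 9.46% and 26.5% and was 73.6% knockdown cells. In NCI-H508 a cluster of shallow barcodes, led by PLCG2 with a median of 1539 UMIs, held 8.76% and 16.0%.

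Interferon genes differed between lines already with the empty vector. The list summed to 7333 CPM in HT29 and 379 CPM in NCI-H508, and to 19659 and 428 CPM with the knockdown. ISG15, a ubiquitin-like effector chosen here after its values were seen, was 1783 and 4417 CPM in HT29 and 53.2 and 57.0 CPM in NCI-H508. A small HT29 cluster led by IFNL1, a type III interferon, and the chemokines CXCL11 and CXCL10 held 46 empty-vector cells (0.466%) and 383 knockdown cells (3.91%), but 0.395% and 2.27% with all variable genes, 0.841% and 4.05% at resolution 1.0, and was not found at resolution 0.3. IFNL1 UMIs were found in 38 and 45 cells of the libraries, 152 and 1001 UMIs in all, and 1 cell held 45.4% of them in the empty-vector and 47.0% in the knockdown library. IFI6 UMIs were found in 69.1% and 97.9% of HT29 cells, unthinned.

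All tests in the paragraphs that follow were chosen after the results were seen. The first pattern is the smaller share of the MUC2-led cluster in the knockdown library of both lines. Dilution by low-UMI barcodes would bring the ratio of shares near 1 among cells of 5000 or more UMIs, but the larger of the lines' ratios there was 0.393 (0.316 to 0.486). Cells under 5000 UMIs were 17.1% and 15.3% in HT29 and 8.81% and 16.9% in NCI-H508, empty vector first. Leaving out so few could hardly bring the ratio near 1, so the test adds little to these shares. In HT29 such cells were the less common in the knockdown library, which argues against this dilution there. Dilution by cycling cells would bring the ratio of shares near 1 among cells called G1. The larger ratio there was 0.492 (0.433 to 0.559), so cycling cells could account for at most a part of the difference. A difference between single libraries other than the knockdown cannot be told apart from it, as there was 1 library per arm and line. A smaller cluster as a response to LSD1 loss is an untested hypothesis, since only shares of single libraries were measured.

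The second pattern is the higher interferon list in the HT29 knockdown library. Library scaling is argued against, since the median log2 ratio of 1.31 was still 1.155 with TMM factors. A small group of strongly responding cells is argued against by a median of 1.308 without the IFNL1-led cluster, and medians within the 9 clusters ran from 0.49 to 1.98. A response to the vector or culture that is not from LSD1 loss cannot be told apart from an effect of LSD1, since the series compared 2 arms with 1 library each. A response to LSD1 loss that needs an interferon pathway already active in the line may explain why NCI-H508 showed none, but this was not tested.

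The third pattern is an NCI-H508 cluster whose 10 leading genes (EAPP, PSMA6, SRP54, BAZ1A and others) all lie within 34432789 to 35932325 of chromosome 14, and whose size depended on the clustering: 168 empty-vector and 269 knockdown cells (4.28% and 6.02%), but 538 and 645 (13.7% and 14.4%) with all variable genes, and 542 and 642 in 2 clusters at resolution 1.0. Extra copies of this segment in a subclone are a candidate explanation. Of the segment's 5 other measured genes, 4 were at least 2-fold higher in the cluster of 437 cells in each library. The median log2 ratio of the 5 over other cells was 2.60 in the empty-vector library and 2.189 in the knockdown library. The rest of the chromosome stood at 0.032 and -0.014. Doublets are argued against by median UMIs at most 1.209 times those of other cells. A scan of windows of 50 genes also placed the highest window of the knockdown over the empty vector in this line here (23559565 to 35932325, median 0.28, against 0.14 for the highest of 100 random gene orders). The cells of these clusters as the whole source of that are argued against, since the segment stood at 0.32 over all cells and at 0.3349 (13 of 14 genes higher) without the 1410 cells that any of the clusterings placed in them, while cells that carry the segment but were placed elsewhere stay open.

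The same scan in HT29 gave a highest window on chromosome 6 (16129125 to 29945884, median 0.33, against 0.29 for random orders) and a lowest on chromosome 19 (36139575 to 40465840, median -0.26, against -0.24), both close to the random range. In NCI-H508 the lowest window was on chromosome 6 (10722915 to 27473118), at -0.10, within the random range, whose lowest value was -0.11.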
